A study of Rattus norvegicus with 4 samples.

How the data were processed

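Total RNA from ventral and lateral prostate of TRAP rats was labelled with the dye Hy5 and hybridized to 1-colour miRNA arrays, per the labels' protocols. Each of the 4 arrays belongs to its own group: ventral saline, ventral OBP-801, lateral saline and lateral OBP-801. Each array's deposited scanner file holds the median intensity of every spot at 635 nm and the median local background intensity, per the file headers, with quality marks for 3 scanner gains. Neither intensity is background-corrected or normalized, which was checked against the blank spots. The array's maker and the scanner software are not given in the sources used here. The series' deposited value table holds intensity values that the authors processed by steps that no label states. Set against the scanner values, each of its columns was a straight line of the spot median. Its zero was the mean of the blank spots after trimming 5% at each end, and its median was 25 on every array. The lowest signals kept were 117.8, 112.7, 118.8 and 123.6, close to the trimmed mean plus 2 SD of 117.6, 112.7, 118.8 and 123.6 but on 2 arrays just below it, and dimmer spots were left empty. The table is therefore linear and scaled on each array's own measured miRNAs, of which there were 355, 310, 342 and 370. It was used as an alternative.

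An array has 3136 spots, of which 679 are miRNA probes, 2278 are blank, 24 are negative controls, 65 carry the name QC-Probe and 8 belong to each spike control. Every miRNA has 1 spot, so no replicate spots were averaged, no technical spread between spots was available for miRNAs, and the planned use of the median of replicate spots was not run. The 8 spots of the first spike control had an SD of 0.04 to 0.20 on the log2 scale across arrays. Background was corrected with limma's normexp and an offset of 50 on all spots, control spots were then left out, 1 spot marked as faulty (miR-26a in ventral saline) was set to missing, and the arrays were quantile-normalized and put on the log2 scale (limma 3.58.1, R 4.3.3). Because of the offset, differences are on the scale of log2 of the corrected signal plus about 50, which understates the change of dim miRNAs. Quantile normalization gives miRNAs of equal rank the same value, so that differences of exactly 0 occur.

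A miRNA counted as detected on an array when its signal was above the mean plus 2 SD of that array's blank spots, a limit of 124, 116, 125 and 129 on the arrays of ventral saline, ventral OBP-801, lateral saline and lateral OBP-801. In that order, negative controls averaged 110.0, 98.5, 111.6 and 115.5, against 101.9, 100.1, 104.1 and 109.4 for the blank spots. They were brighter than blank spots on every array but ventral OBP-801. The limit may therefore pass unspecific signal, and unevenly between arrays, and a limit from the negative controls was not tried. The marks in the scanner files rate spot quality and were not used for detection, except that the 1 spot marked as faulty counted as not detected. A miRNA detected on only 1 array of a pair was given a bound, the bright array's normalized value against the higher of the dim array's own value and the lowest detected value of that array. Names are those of the array's design. The probe that names 2 miRNAs was not named. Names and neighbours of miRNA genes were looked up in the RefSeq annotation of GRCr8, and no coordinates are given because no build is named for the array.

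With 1 array per group, each comparison is a log2 difference of 2 arrays with no p-value, summarised by the counts at least 2-fold higher and lower. The additive fit used limma's lmFit and eBayes on the 242 miRNAs detected on all arrays, with lobe and agent as terms, 1 residual degree of freedom and 2.54 prior degrees of freedom, and Benjamini-Hochberg adjustment. In simulated data with 242 miRNAs and 40 changed in both lobes, this fit recovered 91.2% of 2-fold changes and 19.1% of changes of 1.41-fold, with on average 3.04 and 1.74 false calls. The simulated noise was independent and drawn from the fit's own estimated spread, with no lobe, slide or position effect. Each change was the same in both lobes, so the recovery is a best case. The 22 miRNA lists, matched by mature name, and the rules for naming were fixed before the data were examined. For lists with at least 3 members detected on all arrays, the median was placed among 10000 random lists of the same size matched over 5 bins of mean expression, which describes these arrays only. Random lists draw miRNAs singly, while members of a family or cluster may vary together, so percentiles may look too extreme. A correlation across miRNAs was given with an SD from 2000 bootstrap resamples of miRNAs.

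The miRNAs named were, for each lobe's drug comparison, the 8 largest differences in each direction of at least 2-fold among those detected on both arrays, up to 10 in each direction for both lobes, up to 5 with opposite responses, and the 8 largest of at least 2-fold in each direction for each lobe difference. The rule also took up to 5 bounds per lobe and direction, every miR-320 arm, and up to 4 members of each list with the largest differences. Few passed 2-fold. The miRNAs named at 1.5-fold or 1.2-fold, minor arms, neighbours and other list members beyond these were chosen after their values were seen, and only the largest bound in each direction is given.

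The alternatives were no background correction, plain subtraction, median centring, 75th percentile scaling, no normalization, the deposited value table, no filter on dim probes, a filter at 4 times the detection limit, thresholds of 1.5-fold and 3-fold, a trended prior variance, a fit without the lobe block and lists with the brighter arm only. Subtraction of the blank level without an offset, scaling on spike controls, removal of print block medians or of an intensity trend, the 1.2-fold threshold and the lobe term of the fit were added after the data were seen. The adjustment of p-values over single lists was not planned. The labels give no slide or scan date. The scanner files number the array's position on its slide, which was 1 for both saline arrays and 2 for both OBP-801 arrays.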

Results

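MicroRNA levels were measured in the prostate of male TRAP rats, a transgenic rat model of prostate cancer, after treatment with OBP-801, an inhibitor of histone deacetylases, or with saline. Rats were 6 weeks old at the start and received 2 intravenous injections a week for 8 weeks. The treatment protocol in the labels gives the dose as 1 mg/kg, while the label of the agent gives 1 mg without a body weight. RNA came from the ventral and the lateral prostate, so that 4 arrays filled a design of 2 lobes by 2 agents, with 1 array per group. No group had a replicate. The labels do not say how many rats or which rats each array stands for. Each array carried 1 spot for each of 679 rat miRNA probes, and 299 probes were detected in ventral saline, 290 in ventral OBP-801, 290 in lateral saline and 329 in lateral OBP-801. A set of 242 probes was detected on all 4 arrays, and 300 were detected on none. The brightest miRNA was miR-21 in ventral saline and miR-200b, an epithelial miRNA, on the other arrays. Normalized log2 values of the arrays correlated across all miRNAs with Pearson's r from 0.979 to 0.986, and miRNAs are not independent replicates. The number of arrays, 4, limits the precision of every value below, and all comparisons of single arrays are given without a p-value.

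In the ventral prostate, 2 of the 260 miRNAs detected on both arrays were at least 2-fold higher after OBP-801 than after saline, and 0 were at least 2-fold lower. These were let-7c, of the differentiation-associated let-7 family (MIMAT0000776), and miR-30e*, the minor arm of the miR-30e precursor (MIMAT0004720). The spot signal of let-7c was 3068 in saline and 8922 after OBP-801, a normalized log2 difference of 1.27 or 2.41-fold. That of miR-30e* was 154 in saline and 281 after OBP-801, a difference of 1.12 or 2.17-fold. The major arm, miR-30e, differed the other way, by -0.60. Of the other miRNAs, those furthest below saline were miR-29b, which targets collagens, at -0.87, miR-16, which represses cell cycle genes, at -0.85, and miR-106b, of a proliferation-associated cluster, at -0.84. At 1.5-fold, 7 miRNAs were higher and 10 were lower. The spread of all 260 differences, as an SD scaled from the median absolute deviation, was 0.26 on the log2 scale. It covers both biological and technical differences between the 2 arrays, which the design does not separate. A further 29 miRNAs were detected only after OBP-801, with a largest bound of at least 1.39-fold (miR-484), and 39 only in saline, where the largest bound was at least 1.56-fold (miR-206, a miRNA of striated muscle). The deposited value table, which is scaled on a different set of miRNAs on each array, gave 2 higher and 44 lower miRNAs at 2-fold around a median difference of -0.47. The split was 3 higher and 4 lower with the blank level subtracted and no offset. With no background correction 1 miRNA, let-7c, passed 2-fold, since miR-30e* was at 0.96, and after removal of print block medians miR-30e* was at 0.997.

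In the lateral prostate, 1 of 271 miRNAs detected on both arrays was at least 2-fold higher after OBP-801 and 1 was at least 2-fold lower. The higher was miR-145 (MIMAT0000851), a miRNA of smooth muscle, with a signal of 2821 in saline and 8084 after OBP-801, a difference of 1.14 or 2.20-fold. The lower was miR-182 (MIMAT0005300), of the miR-183/96/182 cluster, with 479 in saline and 260 after OBP-801, a difference of -1.33 or 2.51-fold. The neighbours of miR-182 differed less, with -0.15 for miR-183 and -0.03 for miR-96. At 1.5-fold, 6 miRNAs were higher and 7 were lower, and the spread over all 271 was 0.23. A further 58 miRNAs were detected only after OBP-801, with a largest bound of at least 1.35-fold (miR-412), and 19 only in saline, with a largest bound of 0.58 on the log2 scale (miR-301b). Detection used signals before normalization, and the lateral OBP-801 array had the most miRNAs detected, 329. Set against ventral OBP-801, this array also had 58 miRNAs detected only on it, with 19 only in ventral prostate. The excess may therefore follow this 1 array and cannot be credited to the drug. Without normalization between arrays, or with scaling on the spike controls, the split was 2 higher and 1 lower, and the deposited value table gave 9 higher and 7 lower. It was 3 higher and 7 lower with the blank level subtracted and no offset.

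No miRNA differed at least 2-fold in the same direction in both lobes, where independent lists would share 0.008 higher and 0 lower. At 1.5-fold, miR-3584-5p was higher in both, by 0.80 in ventral and 0.81 in lateral prostate. At this threshold miR-16 was lower in both, by -0.85 and -0.77, as was miR-142-5p, a miRNA of leukocytes, with -0.61 and -0.62. Independent lists of these sizes would share 0.17 higher and 0.29 lower miRNAs. At 1.2-fold, a threshold chosen after the values were seen, 16 miRNAs were higher in both lobes against 4.77 from independent lists, 18 were lower in both against 7.60, and 6 went opposite ways against 12.1. Those higher in both lobes at 1.2-fold included miR-205, a miRNA of basal epithelium, with 0.62 and 0.58, and miR-126, of endothelium, with 0.47 and 0.42. Those lower in both included miR-93, with -0.75 and -0.57, and miR-19a, with -0.63 and -0.50. Across the 242 miRNAs detected on all arrays, the drug differences of the lobes correlated with Pearson's r = 0.43 (bootstrap SD over miRNAs 0.073) and Spearman's rho = 0.47, and 152 had the same sign. The lobes share no array, but both saline arrays lay in position 1 and both OBP-801 arrays in position 2 of their slides, so position and agent cannot be told apart. The r was 0.29 both with no filter on dim probes and with the stricter filter of 4 times the detection limit.

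**Figure D1:**
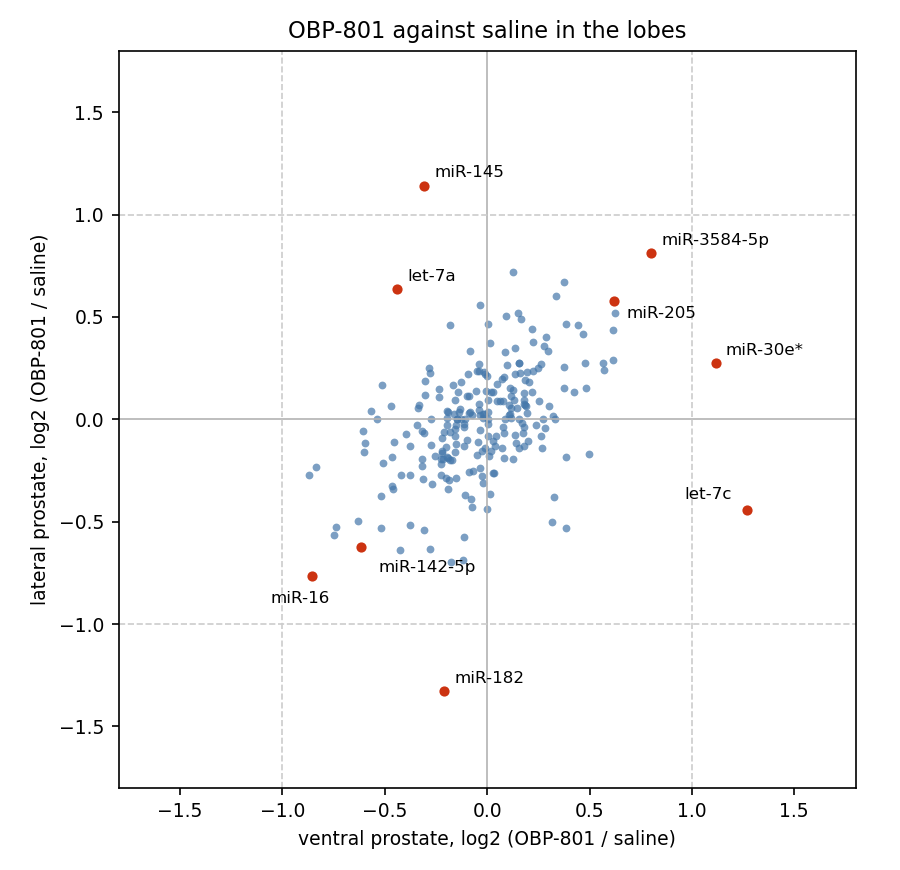
Each point is 1 of the 242 miRNAs detected on all 4 arrays, with the log2 ratio of OBP-801 to saline in ventral prostate on the x axis and in lateral prostate on the y axis. Dashed lines mark 2-fold, red points are miRNAs named in the text, and the points spread along the diagonal with r = 0.43 while let-7c and miR-145 lie away from it.

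The miR-17-92 cluster and its paralogues, miRNAs associated with proliferation, had medians below saline after OBP-801 in both lobes. Of 15 detected members 10 were below 0 in both lobes and 3 above 0 in both, and 0 passed 2-fold. The list's median was -0.38 in ventral prostate, at percentile 0.01 of 10000 random lists matched on expression, and -0.27 in lateral prostate, at percentile 0.095. These percentiles may look too extreme, since the members belong to a few clusters and may vary together, unlike randomly drawn miRNAs. The members with the largest differences were miR-106b, with -0.84 in ventral and -0.23 in lateral prostate, miR-93, miR-19a and miR-20b-5p, which had -0.52 and -0.53. The minor arms miR-92a-2* (0.15 and 0.52) and miR-92b* (0.22 and 0.38) went the other way. The list stayed below the central 95% of random lists in both lobes under 8 of 10 distinct alternatives, where 4 scalings that shift all miRNAs of an array alike, and so leave percentiles equal by construction, count as 1. It lay at percentiles 4.9 and 9.1 with the stricter filter on dim probes and at 2.9 and 0.3 with no filter. Leukocyte markers had medians of -0.15, at percentile 13.5, and -0.17, at percentile 9.2, beside these values, and they lay at percentiles 2.02 and 1.86 with the blank level subtracted and no offset. Stromal markers lay at percentiles 97.1 and 99.4.

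The androgen-responsive miRNAs, reported as targets of the androgen receptor in prostate cells, also had medians below 0 in both lobes, of -0.27 in ventral (percentile 1.1) and -0.22 in lateral prostate (percentile 1.1) over 10 members, of which 6 were below 0 in both. Within this list miR-19a, which also belongs to the previous list, had the largest difference. The epithelial miR-141 had -0.60 and -0.16, and miR-101a, which targets EZH2, had -0.45 and -0.11. The remaining large difference, of miR-125b-5p, ran from 0.31 in ventral to -0.50 in lateral prostate. The list stayed below the central 95% of random lists in both lobes under 4 of 10 distinct alternatives, counted in the same way. It was at percentiles 44.9 and 6.4 with no filter on dim probes, 18.6 and 22.2 with the stricter filter, 6.1 and 10.4 with the brighter arm only and 8.6 and 1.6 with the blank level subtracted and no offset. Of the 78 probes of the imprinted Dlk1-Dio3 cluster, 12 were detected on all 4 arrays. Their medians were 0.14 in ventral (percentile 98.7) and 0.19 in lateral prostate (percentile 99.7). Beside both lists, stromal markers lay at percentiles 97.1 in ventral and 99.4 in lateral prostate, and epithelial markers at 18.4 and 49.5. Of the 12, 8 were above 0 in both lobes, 3 were below 0 in ventral and 2 in lateral prostate, and 0 passed 2-fold. Examples were miR-665, with 0.62 and 0.44, and miR-667, with 0.29 and 0.40, while miR-494 had -0.18 and 0.46 and miR-770* 0.32 and 0.01. The cluster stayed above the central 95% in both lobes under 6 of 9 distinct alternatives. The stricter filter is not among these, since it left fewer than 3 members. Its lateral percentile was 85.2 with no filter, 91.7 after removal of print block medians and 94.1 in the deposited value table, which ends the lateral call in each. In the deposited value table the cluster's ventral median was -0.20, above the median of -0.47 over all miRNAs.

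**Figure D2:**
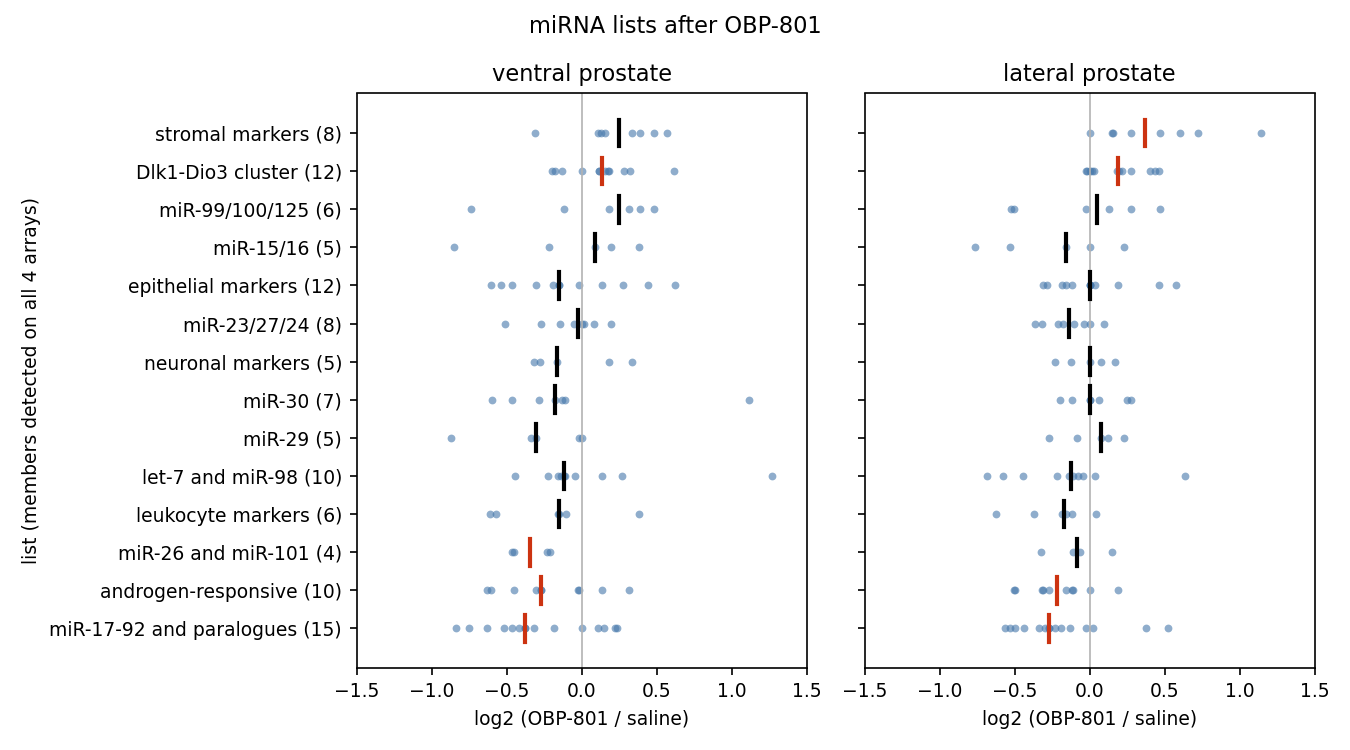
Points are the log2 ratios of OBP-801 to saline of each list's members detected on all 4 arrays, in ventral (left) and lateral prostate (right), with the number of members beside each list's name. Bars mark medians, in red where the median lies outside the central 95% of 10000 random lists, as for miR-17-92 and paralogues with -0.38 and -0.27.

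Among the cell type markers, the stromal miRNAs of smooth muscle and fibroblasts had medians of 0.25 in ventral (percentile 97.1) and 0.37 in lateral prostate (percentile 99.4), and 6 of 8 were above 0 in both lobes. They lay above the central 95% in both lobes under 1 of 10 distinct alternatives, the scalings by a constant per array, at 98.7 and 99.9. Over the alternatives the ventral percentile went down to 94.3, and the lateral one to 94.4 with the stricter filter, which ends the lateral call. Besides miR-145, these were led by miR-143* (0.13 and 0.72), miR-214 (0.34 and 0.60) and miR-199a-3p (0.57 and 0.27). The major arm miR-143, the neighbour of miR-145, had 0.16 in ventral and 0.00 in lateral prostate. The 12 epithelial markers had medians of -0.15 and 0.00, at percentiles 18.4 and 49.5, with members going both ways. In ventral prostate miR-200a had -0.54 and miR-200c -0.47, beside the higher miR-205, and in lateral prostate they had 0.00 and -0.18. In the leukocyte list miR-142-5p was lower in both lobes, miR-223 had -0.57 in ventral and 0.04 in lateral prostate, miR-150 had 0.38 and -0.18, and miR-146a had -0.11 and -0.37. The endothelial miR-126* had 0.11 and 0.07. The muscle miRNA miR-133b had 0.26 and 0.27 and miR-133a 0.03 and -0.26. Erythroid miR-451 had -0.04 and 0.56. The neuronal list had medians of -0.17 and 0.00, at percentiles 14.9 and 44.3, with -0.32 and -0.23 for miR-9. The liver miRNA miR-122 was not detected.

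Among the families, miR-26 and miR-101 had a ventral median of -0.34 over 4 members (percentile 0.26), led by miR-26b with -0.46, and a lateral median of -0.09 (percentile 16). Its ventral percentile was 7.8 in the deposited value table and 4.65 with the blank level subtracted and no offset, which ends the ventral call. The miR-29 family had a median of -0.31 in ventral (percentile 4.48) and 0.07 in lateral prostate (percentile 80). Its ventral percentile was 2.47 after removal of print block medians, just outside the central 95%, and 47.9 with no filter. The let-7 family with miR-98 had medians of -0.12 (percentile 31.8) and -0.13 (percentile 7.3). Its ventral median was 0.05 (percentile 67.2) under median centring, and its lateral median was 0.11 (percentile 20.0) with no normalization. The family's lateral percentile was 1.39 with the blank level subtracted and no offset, outside the central 95%. Its member let-7a had -0.44 and 0.64, let-7f -0.12 and -0.69, and let-7d -0.11 and -0.58. The family of miR-99, miR-100 and miR-125 had 0.25 (percentile 95.4) and 0.05 (percentile 69.1), with miR-99a at 0.48 and 0.28, miR-100 at 0.39 and 0.47 and miR-125a-3p at -0.74 and -0.53. This family's ventral percentile was 98.67 with the stricter filter and 97.54 after removal of print block medians, both outside the central 95%. It was 91.8 in the deposited value table. The miR-15/16 family had 0.09 (percentile 71.8) and -0.16 (percentile 16.2), with miR-15b at 0.38 and -0.53 against the lower miR-16. Its lateral median was -0.53 (percentile 1.04) with the stricter filter, outside the central 95%, and 0.07 (percentile 21.5) with no normalization. The miR-30 family had -0.18 (percentile 21.4) and 0.00 (percentile 51.4), and the miR-23/27/24 clusters -0.02 (percentile 56.4) and -0.14 (percentile 11.6), with miR-23b at -0.51 and -0.21. Fewer than 3 members were detected of the remaining families. Their values were -0.22 and -0.27 for miR-34a, -0.19 and -0.19 for miR-221, -0.17 and -0.20 for miR-222, -0.07 and -0.43 for miR-181a, and -0.09 and -0.26 for miR-181b. Of the 14 lists with at least 3 detected members, 4 lay outside the central 95% of random lists in ventral and 4 in lateral prostate, and 3 did so on the same side in both.

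The published work on this compound in these rats concerns miR-320, which lowers the androgen receptor. The major arm miR-320 (MIMAT0000903) had a spot signal of 196 in ventral saline, 175 in ventral OBP-801, 201 in lateral saline and 235 in lateral OBP-801. Its normalized log2 differences were -0.11 in ventral and -0.04 in lateral prostate, within the spread of all miRNAs of 0.26 and 0.23. The minor arm miR-320* (MIMAT0017168) had 0.13 in ventral and 0.35 in lateral prostate. Its signal was close to the detection limit, with 132 in lateral saline against a limit of 124.6 and 189 in lateral OBP-801 against 129. In ventral prostate its signal was 156 in saline and 158 after OBP-801. With the blank level subtracted and no offset, the lateral difference of miR-320* was 1.11. In the deposited value table it was 1.33, where the lateral median over all miRNAs was shifted by 0.15. These 2 alternatives are given for the lateral miR-320* only, so they show no rise of the major arm or in ventral prostate.

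With both lobes in an additive fit, in which the lobe was a block, 0 of 242 miRNAs passed an adjusted p of 0.05 for OBP-801 against saline (limma, Benjamini-Hochberg), and 40 passed an unadjusted p of 0.05, 20 higher and 20 lower, where 12.1 are expected by chance. No spread is given for the 12.1, since miRNAs are not independent. An effect of slide position, which cannot be told apart from the agent, could give the same excess. The smallest adjusted p, 0.153, was shared by 9 miRNAs. Among these were miR-3584-5p, at 0.81 (SE 0.087), miR-16, at -0.81 (SE 0.090), and miR-142-5p, at -0.62 (SE 0.087). Also among them were miR-205, at 0.60 (SE 0.088), and miR-93, at -0.66 (SE 0.10). Each had the same direction in 2 of 2 lobes. The fit favours such miRNAs, since its residual is the difference between the lobes' responses, so this agreement is no further evidence. Adjusted over the list alone, 3 members of the miR-17-92 list passed (miR-93, miR-19a and miR-20b-5p), 2 of the family of miR-99, miR-100 and miR-125 (miR-125a-3p and miR-100) and 1 each of the miR-15/16 (miR-16), epithelial (miR-205), endothelial (miR-126) and leukocyte lists (miR-142-5p), while 0 passed in each of the other lists. That adjustment was not planned, was made separately in each list and was not corrected over lists. The endothelial list held only 2 detected members. Over all 242 miRNAs 0 passed, as given above. The fit has 1 residual degree of freedom, and the arrays of the lobes may come from the same rats, so its p-values may be too small. The count over all miRNAs ran from 0 to 30 over other processing, with 30 under 75th percentile scaling, 9 without background correction and 0 under median centring.

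Between the lobes, miR-133b, a miRNA of striated muscle, was higher in lateral than in ventral prostate under both agents, by 1.09 or 2.14-fold in saline and 1.10 or 2.15-fold after OBP-801. With no background correction it was at 0.93 and 0.96, below 2-fold under both agents. Another muscle miRNA, miR-1, was detected only in lateral prostate under both agents, at least 1.78-fold higher in saline and at least 1.59-fold higher after OBP-801. The leukocyte miRNA miR-223 was lower in lateral prostate, by -1.46 in saline, where it was the only one of 255 miRNAs at least 2-fold lower, and by -0.84 after OBP-801. Each lobe difference shares its arrays with the drug comparisons, so the next 4 values are not further evidence of a change. In saline, let-7c (1.53) and miR-30e* (1.05) were at least 2-fold higher in lateral prostate, and after OBP-801 they differed by -0.18 and 0.21. Both rest on the ventral saline array, where let-7c had a normalized log2 value of 11.95 against 13.03 to 13.48 on the other arrays. After OBP-801, of 271 miRNAs, miR-145 was at least 2-fold higher in lateral prostate (1.09) and miR-182 lower (-1.21), both on the lateral OBP-801 array that gave their drug differences. The leukocyte markers as a list had medians, lateral minus ventral, of -0.47 in saline (percentile 0.07) and -0.50 after OBP-801 (percentile 0.02). Epithelial markers had medians of 0.16 (percentile 97.1) and 0.27 (percentile 99.6). The miR-15/16 family had 0.38 in saline (percentile 98.6) and -0.01 after OBP-801 (percentile 40.5), and the miR-30 family 0.14 (percentile 89.5) and 0.27 (percentile 98.3). The lobe differences under the 2 agents correlated across 242 miRNAs with r = 0.50 and rho = 0.41. Both arrays of each lobe difference had the same slide position, so they lay on different slides. A difference between slides cannot be told apart from one between lobes in these values. The lobe term of the additive fit, examined after the values were seen, had 0 of 242 miRNAs past an adjusted p of 0.05 (limma, smallest 0.0898) and 40 past an unadjusted p of 0.05. In saline 3 miRNAs were at least 2-fold higher and 1 lower, against 6 and 13 in the deposited value table and 7 and 6 with the blank level subtracted and no offset. Only let-7c was higher, and 1 lower, with no background correction and after removal of print block medians. After OBP-801 the split was 2 and 1, against 8 and 0 without normalization or with scaling on the spike controls and 46 and 1 in the deposited value table. It was 7 and 10 with the blank level subtracted and no offset, and 1 and 1 with no background correction.

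**Figure D3:**
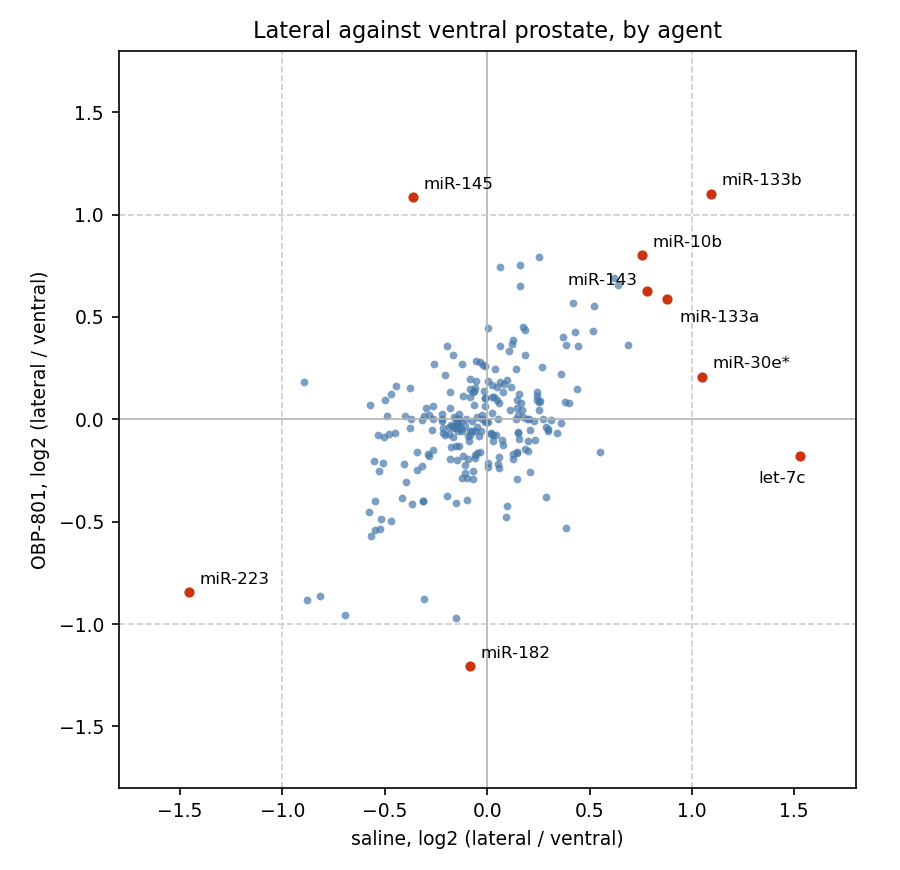
Each point is 1 of the 242 miRNAs detected on all 4 arrays, with the log2 ratio of lateral to ventral prostate in saline on the x axis and after OBP-801 on the y axis. Dashed lines mark 2-fold, red points are miRNAs of muscle, stroma, leukocytes or the drug comparison, and miR-133b lies at 1.09 and 1.10 while let-7c lies at 1.53 and -0.18.

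The responses of the lobes to OBP-801 differed by at least 2-fold for 4 of 242 miRNAs. The response was larger in lateral prostate for miR-145, by 1.45 on the log2 scale, and for let-7a, by 1.08. It was lower in lateral prostate for let-7c, by -1.71, and for miR-182, by -1.12. The design leaves no degree of freedom to test these differences, and the spread of all 242 was 0.25. The probes of let-7a and let-7c target closely related sequences, and their differences were opposite in sign in each lobe. The lateral difference of let-7c of -0.44 was 0.21 without normalization, and the ventral difference of miR-145 of -0.31 was 0.20 under median centring and 0.13 without normalization.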

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

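All tests of explanations in this part were chosen after the results were seen. The lobes went opposite ways after OBP-801 for let-7c, with a lateral response minus ventral response of -1.71 on the log2 scale, for miR-145, with 1.45, and for let-7a, with 1.08. These differences were not tested, since no group has a replicate. The direction in the lobe with the smaller change depends on scaling for let-7c in lateral prostate (-0.44, against 0.21 without normalization) and for miR-145 in ventral prostate (-0.31, against 0.13), and it held for let-7a under the 12 other settings that gave a value. Spots named QC-Probe, which no comparison uses, were above the detection limit on all 4 arrays at 13 of 65 positions.

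The drug differences of the lobes correlated across miRNAs with r = 0.43. Removal of print block medians left r at 0.36, and removal of an intensity trend left it at 0.43, both above 2 bootstrap SDs of 0.073, which argues against either as the whole cause. The array's position on its slide cannot be told apart from the agent, because 0 slide positions held arrays of both agents. The 13 QC-Probe spots correlated between the lobes with r = 0.47. No spread was computed for this value and what these spots measure is not known, so it decides nothing. Blank spots, which should hold no miRNA signal, correlated with r = 0.17, so a shared technical part may be present. A response to OBP-801 common to the lobes stays open beside it.

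The 4 miRNAs that differed at least 2-fold in 1 lobe were let-7c and miR-30e* in ventral and miR-145 and miR-182 in lateral prostate. All 4 stayed at least 2-fold apart under the 4 other scalings. These shift all miRNAs of an array alike, so they amount to 1 alternative with different shifts. The values argue only against a constant shift of the size these scalings span, and do not cover scaling that varies with intensity. The call of miR-30e*, at 1.12 as reported, ended with no background correction (0.96) and after removal of print block medians (0.997), since it lies close to 2-fold. A fault of single spots may remain, since the median of 7 neighbouring miRNAs and other arms, signed along each miRNA's own difference, was 0.030. These partners went both ways, from 0.72 for miR-143* beside miR-145 to -0.60 for miR-30e beside miR-30e*, so the test decides nothing. The neighbour of let-7c, miR-99a, had 0.48, while miR-143, the other arm beside miR-145, had 0.00. A response of 1 lobe to the drug was not tested.

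For the miR-17-92 list, with medians below 0 in both lobes, removal of print block medians left percentiles of 0.21 and 0.07, which argues against unevenness between print blocks as the whole cause. Cross-hybridization among the 5 members with the miR-17 seed could not be excluded: the 10 members with other sequences lay at percentiles 27.1 in ventral and 3.66 in lateral prostate, and the 6 major arms among these at 0.59 and 6.84. A smaller share of leukocytes, in which these clusters are abundant, may contribute, and it stays open: the leukocyte markers lay at percentiles 13.5 and 9.2 as reported, and over the alternatives from 2.02 to 14.7 in ventral and from 1.86 to 9.75 in lateral prostate, below 2.5 in both lobes with the blank level subtracted and no offset. Slide position is confounded with the agent here too, and a drug effect on these clusters stays open as untested.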

How the results depend on the processing

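The alternatives that subtracted the blank level without an offset, scaled on spike controls or removed print block medians or an intensity trend were chosen after seeing the data. No named miRNA at least 2-fold apart in a comparison changed direction there under any alternative. Of 121 values for counts, the correlation and the lists under alternatives 76 were within the limits set and 45 moved, as did 114 of 604 values of single miRNAs and list medians. In the order ventral, lateral, lobe difference in saline and lobe difference after OBP-801, the counts at 2-fold were 2, 2, 4 and 3 as reported. They were 17, 13, 14 and 18 at 1.5-fold (3 in both lobes), 0, 0, 0 and 0 at 3-fold, and 1, 1, 1 and 1 with the stricter filter, which leaves 63, 70, 65 and 70 miRNAs. The deposited value table gave 46, 16, 19 and 47, with 2 in both lobes and 58 differences between the lobes' responses against 4. Its medians over all miRNAs were shifted by -0.47, 0.15, -0.10 and 0.50, which its scaling on a different set per array produces. The blank level without an offset gave 7, 10, 13 and 17, and 13 differences between responses. No background correction gave 1 in ventral prostate and 2 between lobes in saline, as did removal of print block medians, and without background correction 2 remained between lobes after OBP-801. No normalization and spike scaling each gave 8 between lobes after OBP-801, where they shift the median by 0.28, and by 0.19 and 0.12 in lateral prostate, and spike scaling also by 0.12 between lobes in saline. The cause of the other changes was not tested. The correlation of the lobes' responses was 0.53 under median centring, 75th percentile scaling, no normalization and spike scaling, which are equal by construction, 0.29 with no filter and 0.29 with the stricter filter. The additive fit called 30 miRNAs under 75th percentile scaling (18 higher, 12 lower), 9 with no background correction, 4 without normalization, 3 with the blank level and no offset, 2 with the stricter filter and 1 with spike scaling, and 0 under the 8 others; of the 30, 25 were among the 40 past an unadjusted p of 0.05 as reported. The smallest adjusted p ran from 0.00315 to 0.453. The number of lists outside the central range on the same side in both lobes, 3 as reported, was 0 with no filter, 0 with the stricter filter, 1 after removal of print block medians, 2 with the brighter arm only, with the deposited value table and after removal of an intensity trend, and 4 under the 4 scalings by a constant, which add the stromal markers. It was 3 with the blank level and no offset, where the leukocyte markers take the place of the androgen-responsive miRNAs. The medians of the miR-17-92 and androgen-responsive lists were below 0 in both lobes under all settings. In ventral prostate the sign says little for the deposited value table, where the shift of -0.47 put even the stromal median below 0, at -0.03. The androgen-responsive median was close to 0 in ventral prostate with no filter, at -0.02. It was -0.009 in lateral prostate with no normalization, where all miRNAs had a median of 0.19. Leaving out an array leaves no residual degree of freedom, so that the fit was not run and the remaining lobe's difference is the value given in the report. Signals limit what can be seen, since 300 of 679 miRNAs were not above the blank limit on any array. The additive fit compares the agents within each lobe, and without this lobe block it called 0 of 242, with 27 past an unadjusted p of 0.05 against 40.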

Other observations

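Other miRNAs differed between the lobes in the same direction under both agents, named here after their values were seen. In lateral prostate miR-10b, of stroma, was higher by 0.76 in saline and 0.80 after OBP-801 and miR-143 by 0.78 and 0.63. The stromal list as a whole had medians of -0.11 (percentile 32.1) and 0.05 (percentile 69.5), and the other arm, miR-143*, had -0.50 and 0.10. Also higher in lateral prostate was the muscle miRNA miR-133a, by 0.88 and 0.59. The p53-responsive miR-34a was lower in lateral prostate, with -0.82 and -0.87, as were miR-146a of leukocytes, with -0.69 and -0.96, and the pair miR-221 (-0.57 and -0.57) and miR-222 (-0.47 and -0.49), which targets the cell cycle inhibitor p27. These values have no replicate and compare arrays on different slides, so a difference between slides may be part of them. For each miRNA with the same sign under both agents the direction held under the other settings that gave a value.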
